A study of Mus musculus with 2 samples.

How the data were processed

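Small RNA libraries from C2C12 myotubes, differentiated for 72 h, were analysed as 1 group of 2 biological replicates, following the labels. The deposited tables hold raw read counts per miRNA gene that the authors made against the mm10 assembly and annotation release M21, per the text deposited with the files. The aligner, the counting program, adapter trimming and any filter on the reads are not given in the sources used here. Each table has 3 columns of counts (strand ignored, the gene's own strand, and the opposite strand) and 4 summary lines for unmapped, multimapping, no-feature and ambiguous reads. The column for the gene's own strand was read from the values: it held nearly all gene reads, and the opposite-strand column held reads almost wholly at genes that overlap a miRNA gene on the other strand. Multimapping reads were counted in their own line, so gene counts leave out reads that mapped to several places.

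The summary lines name no gene and were left out of library sizes and tests. In replicate 1 multimapping reads were 22.0%, unmapped reads 22.7% and no-feature reads 5.88% of 15349205 reads. In replicate 2 they were 17.9%, 23.1% and 5.57% of 18450359 reads. Ambiguous reads, which arise when strand is ignored, were 4.83% and 8.05%, because 32 pairs of miRNA genes overlap on opposite strands. All 2202 gene identifiers matched GENCODE release M21, whose GRCm38 assembly is mm10, and coordinates, host genes and hairpin sequences were taken from it. Coordinates are 1-based.

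CPM were computed with the reads assigned to miRNA genes on the sense strand as the total. A gene was called detected at 2 CPM or more in both libraries. Correlations used log2(CPM + 1). The biological coefficient of variation was the square root of the common dispersion from edgeR 4.0.16 (estimateDisp, intercept only) in R 4.3.3. Differences between the libraries were tested per gene with an exact two-sided binomial test using TMM effective library sizes, with Benjamini-Hochberg adjustment over genes with 10 or more reads in total and a threshold of 0.05. With no condition to contrast, edgeR's quasi-likelihood test was not used. Ratios between miRNAs used a pseudocount of 0.5 reads. Shares have 95% exact Clopper-Pearson intervals. Tests in Python 3.11.15 used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

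A set of 15 lists of miRNA genes, the tests in the report, the rule for named genes and the alternatives were fixed before the data were examined. The adjustment over each list alone and the counts of genes that differed 2-fold or more were added later, and most tests of explanations in the closing section were written later, as stated there. The lists were the myomiRs, the myogenic modulators, the let-7 family, the Mir17 cluster and its paralogs, and the Dlk1-Dio3 locus. Others held miRNAs associated with fibroblasts and smooth muscle, and markers of blood cells, neurons, epithelium, endothelium, liver and pancreas, and embryonic stem cells. The rest were genes with identical copies, their single-copy relatives, and annotated genes that by repute overlap other small RNAs. Of 292 list entries, 9 had no match, all in the last list, and 4 of the 231 distinct symbols were matched through RefSeq synonyms chosen after the identifiers had been seen. The named genes were the 20 with the highest mean CPM, the 4 most abundant detected members of each list, every myomiR, and the 10 with the largest difference between libraries among genes with a mean of 10 CPM or more and an adjusted p below 0.05. The members of the ratios were also fixed beforehand. Mir10b and Mir126b were named outside these rules after their counts were seen, as were genes outside them that appear only in the closing section. Very small exact p-values were below the range of the software and are not printed. Lists were placed among 10000 random lists of the same size, as a description of these libraries.

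Alternatives were the count that ignores strand, all reads as the denominator, each library left out, other thresholds for detection and testing, other pseudocounts, DESeq2 1.42.0 size factors or library totals in place of TMM, and shares without the most abundant gene. The binomial test was tested on simulated data with counting error only and known totals in place of TMM. In this simulation of the comparison between the libraries, with 420 genes tested, 55% of genes changed 1.5-fold and 67% of genes changed 2-fold were called, and 1.29% of 233 unchanged genes were called. A simulated coefficient of variation of 0.4 was recovered as 0.406 over 274 genes.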

Results

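MicroRNAs were sequenced from myotubes made from C2C12, a mouse myoblast line that fuses into multinucleated muscle fibres when it differentiates in culture. The cells had been differentiated for 72 h. The series held 1 group of 2 libraries, labelled biological replicates 1 and 2 and drawn from separate biosamples, each with 1 technical replicate. The labels give a size range below 30 without a unit, name the work as an evaluation of RNA, and list no treatment or undifferentiated control. Values were therefore compared between miRNA genes within the group and between the 2 libraries.

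Replicate 1 held 15349205 reads, of which 7581366 (49.4%) were counted on the sense strand of a miRNA gene. Replicate 2 held 18450359 reads, of which 9865298 (53.5%) were so counted. The 95% exact Clopper-Pearson intervals of these shares ran from 49.37% to 49.42% and from 53.45% to 53.49%. Intervals and detection floors given here cover counting error of reads within each library only. The labels mention no molecular identifiers, so the counts are of reads and not of molecules. A count of 3 corresponded to 0.396 counts-per-million (CPM, relative to miRNA-assigned reads) in replicate 1 and to 0.304 CPM in replicate 2.

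The first question was which miRNAs the 72 h myotubes carried. Mir206, a skeletal muscle miRNA, was the most abundant miRNA gene in both libraries, at 378817 ± 53707 CPM (SD, n = 2), or 34.1% of miRNA reads in replicate 1 and 41.7% in replicate 2. Mir378a, which lies in an intron of the metabolic coactivator gene Ppargc1b, followed at 112998 ± 36038 CPM (SD, n = 2). Mir21a at 60909 ± 30275 CPM, Mir22 at 54496 ± 9490 CPM and Mir143 at 35574 ± 15314 CPM (SD, n = 2) had the next highest means. Their order was not resolved. In replicate 2, Mir22 (61207 CPM) was above Mir21a (39501 CPM). Mir143 (24746 CPM) was there below Mir99a (27699 CPM) and Mirlet7b (27399 CPM). The lower Mir206 value, 340841 CPM in replicate 1, exceeded the higher Mir378a value, 138481 CPM in replicate 2, so these genes were separated by more than the replicate spread. Mir99a was the most even of the 6 leading genes, at 28592 ± 1263 CPM (SD, n = 2). Mir23a, Mirlet7b, Mirlet7i and Mir322 had means of 26596, 22969, 20538 and 20298 CPM with SDs of 3628, 6265, 9967 and 10297 CPM (n = 2), and their order was not resolved by 2 libraries. Mir130a, Mir133b, Mir23b, Mir99b, Mir140, Mir351, Mir100, Mir27b, Mir149 and Mir532 completed the 20 most abundant genes, from 16401 ± 3465 CPM for Mir130a to 7253 ± 2492 CPM for Mir532 (SD, n = 2). The counts of Mir378a, Mir23a, Mir133b, Mir23b and Mir27b are uncertain. Their hairpins share an exact run of 20 or more bases with another annotated miRNA hairpin. The ranking and shares cover assigned reads only, so miRNAs whose reads mapped to several places may rank too low.

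The reads assigned to miRNA genes were concentrated in few genes. Multimapping reads, left out of the shares below, came to 0.446 of the assigned reads in replicate 1 and 0.334 in replicate 2. The 20 most abundant genes of each library took 84.4% of miRNA reads in replicate 1 and 88.5% in replicate 2, and 18 genes were among the 20 in both. Of 2202 annotated miRNA genes, 274 reached 2 CPM in both libraries, 65 reached a mean of 1000 CPM, and 1494 had no read in either library.

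**Figure D1:**
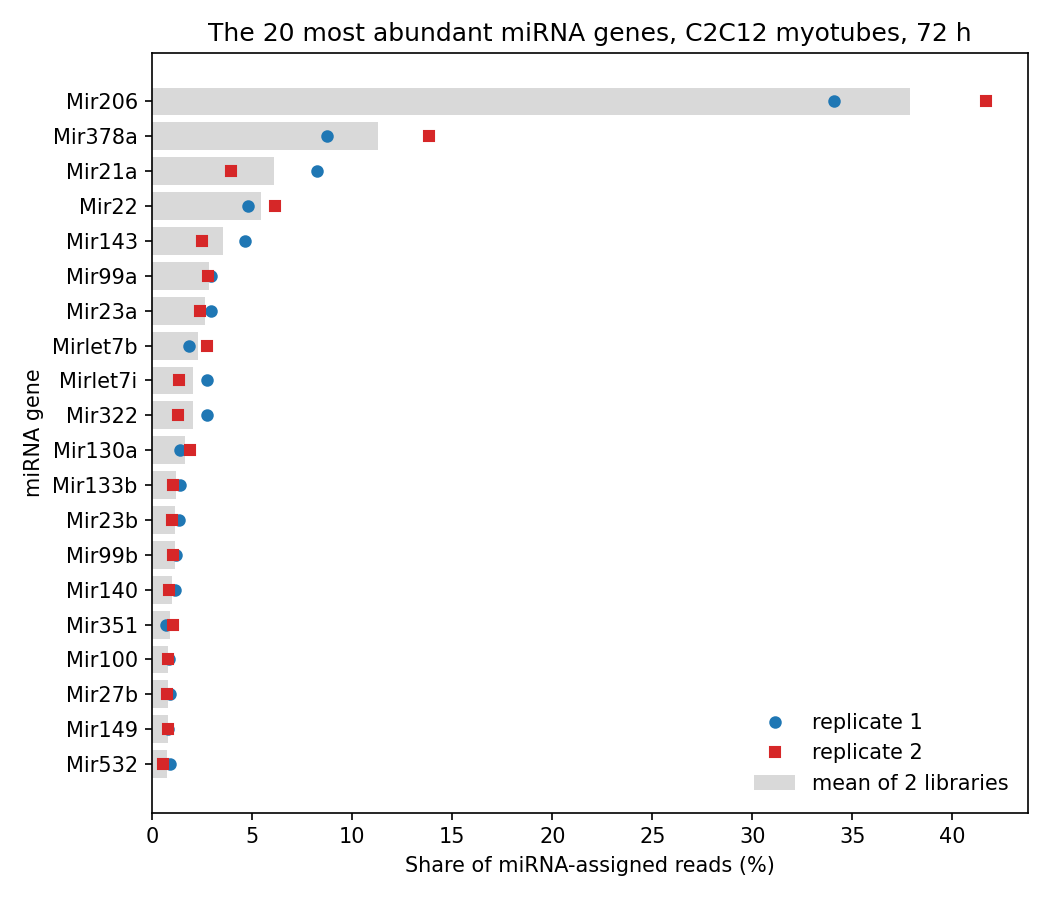
Share of miRNA-assigned reads (%, horizontal axis) for the 20 miRNA genes with the highest mean CPM. Bars give the mean of the 2 libraries, circles replicate 1 and squares replicate 2; Mir206 stands apart at 34.1% and 41.7%.

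Mir206 and Mir133b lie in the same long non-coding RNA gene. On the mm10 assembly, Mir206 (ENSMUSG00000065559.1) occupies chromosome 1 from 20679010 to 20679082 on the plus strand, within an exon of Gm28653. Its annotated hairpin is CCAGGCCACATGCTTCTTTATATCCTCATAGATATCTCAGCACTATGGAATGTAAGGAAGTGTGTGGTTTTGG. Mir133b (ENSMUSG00000065480.1) occupies chromosome 1 from 20682769 to 20682887 on the plus strand, also within an exon of Gm28653. Its annotated hairpin is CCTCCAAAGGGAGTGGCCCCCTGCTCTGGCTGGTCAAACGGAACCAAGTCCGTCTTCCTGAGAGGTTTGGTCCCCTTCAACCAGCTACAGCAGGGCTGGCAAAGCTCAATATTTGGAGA. Mir206 at 378817 ± 53707 CPM and Mir133b at 12089 ± 2151 CPM (SD, n = 2) were further apart than the spread of either. Mir21a (chromosome 11, 86584067 to 86584158, minus strand) overlaps an exon of Vmp1, Mir22 (chromosome 11, 75463716 to 75463810, plus strand) an exon of Mir22hg, and Mir99a (chromosome 16, 77598936 to 77599000, plus strand) an intron of Mir99ahg. Mir378a (chromosome 18, 61397835 to 61397900, minus strand) and Mir143 (chromosome 18, 61649196 to 61649258, minus strand) were the other leading genes, and Mir143 overlaps no annotated protein-coding or long non-coding gene.

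The muscle-enriched miRNAs (myomiRs) made up 35.5% of miRNA reads in replicate 1 and 42.8% in replicate 2, or 39.2% ± 5.16 (SD, n = 2). The listed Mir1a, Mir133a, Mir486 and Mir3107 genes have identical copies, so this share leaves out their reads that mapped to several places. Mir206 alone made up 37.9% of miRNA reads on average. Mir133b gave 12089 ± 2151 CPM. Mir499 gave 471 ± 131 CPM and Mir208b gave 378 ± 166 CPM (SD, n = 2). These lie in introns of the myosin heavy chain genes Myh7b and Myh7. Mir208a, in an intron of the cardiac myosin gene Myh6, was at 10.3 ± 4.50 CPM, and Mir486, in an intron of Ank1, was at 30.9 ± 0.294 CPM (SD, n = 2). Mir3107, on the strand opposite Mir486, was at 7.09 ± 3.87 CPM. Mir486 and Mir3107 are listed as identical copies, so both values leave out reads that mapped to several places and are uncertain. The copies of the muscle miRNAs Mir1a and Mir133a were low, with 3.02 ± 1.69 CPM for Mir1a-2, 2.94 ± 0.138 for Mir1a-1, 2.01 ± 1.17 for Mir133a-1 and 1.03 ± 0.0294 for Mir133a-2 (SD, n = 2). Each of these 4 genes shares a run of 20 or more bases with another miRNA hairpin, and reads that mapped to several places were counted outside the genes, so their values are uncertain and are no measure of mature Mir1a or Mir133a. The median log2(CPM + 1) of the myomiR list lay at the 99.97th percentile of 10000 random lists of the same size drawn from all annotated miRNA genes. Most annotated genes had no read, and this percentile does not set the list apart: neuronal (99.87th), epithelial (99.62nd) and blood-cell (98.65th) lists, which took few reads, also ranked high.

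Among miRNAs reported to modulate myoblast proliferation or differentiation, 31 of 32 reached 2 CPM in both libraries. Their median lay at the 100th percentile of random lists, with the limit given above for the myomiR percentile. Together they took 17.8% ± 1.91 of miRNA reads (SD, n = 2). Mir378a accounted for most of that share, followed by Mir322 at 20298 ± 10297 CPM, Mir351 at 8764 ± 2417 CPM and Mir27b at 7874 ± 1086 CPM (SD, n = 2). The Mir24, Mir26a, Mir29b, Mir125b, Mir181a and Mir181b genes, Mir128-1, Mir450-1 and Mir450-2 of this list have identical copies. The share and the order of members leave out their reads that mapped to several places. In the count that ignored strand, where Mir378a was listed at 0, the share of this list was 7.06%.

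Ratios between related miRNAs had the same direction in both libraries. Mir206 exceeded the summed Mir1a copies by 15.97 ± 0.65 on the log2 scale and Mir133b exceeded the summed Mir133a copies by 11.96 ± 0.79 (SD, n = 2). The counts of the copies are uncertain, as given above, because they leave out reads that mapped to several places. Neither ratio is a measure against mature Mir1a or Mir133a, in direction or in size. Within shared clusters, Mir322 exceeded Mir503 by 4.06 ± 0.44, Mir221 exceeded Mir222 by 2.54 ± 0.60 and Mir143 exceeded Mir145a by 3.96 ± 0.92 (log2, SD, n = 2). The Mir199a copies plus Mir199b were below Mir214, with a log2 ratio of -4.81 ± 0.77 (SD, n = 2); Mir199a-1, Mir199a-2 and Mir199b each share a run of 20 or more bases with another miRNA hairpin and Mir214 does not, so this ratio is uncertain in the same way. A two-sided exact paired permutation test on 2 libraries cannot give a p below 0.5, so no test was made of these ratios.

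The next comparison set other preset groups beside the muscle miRNAs. Fibroblast- and smooth-muscle-associated miRNAs took 19.5% ± 3.75 of miRNA reads (SD, n = 2), led by Mir21a, Mir22, Mir143 and Mir99a, and 14 of 16 members reached 2 CPM in both libraries. The member Mir10b had no read in either library, which allows up to 0.396 CPM in replicate 1 and 0.304 CPM in replicate 2. The let-7 family took 5.11% ± 0.829, with all 12 members above 2 CPM in both libraries and Mirlet7b and Mirlet7i ahead of Mirlet7g at 2945 ± 2438 CPM and Mirlet7d at 2240.2 ± 827 CPM (SD, n = 2). The Mirlet7a, Mirlet7c and Mirlet7f genes have identical copies, and their counts, the share and the order of members leave out reads that mapped to several places. The Mir17 cluster and its paralogous clusters, which are linked to proliferation, took 1.10% ± 0.391 (SD, n = 2), led by Mir17 at 5138 ± 2102 CPM, Mir93 at 2251 ± 324 CPM, Mir106b at 1695 ± 579 CPM and Mir18 at 747 ± 320.1 CPM (SD, n = 2). The same limit holds for the Mir199a, Mir199b and Mir196a genes of the fibroblast list and the Mir19b and Mir92 genes of the Mir17 list. The medians of the fibroblast, let-7 and Mir17 lists each lay at the 100th percentile of random lists. The list of genes with identical copies did so too, and this percentile does not set these lists apart, because most annotated genes had no read.

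Marker miRNAs of other cell types were scarce. Blood-cell miRNAs took 0.0149% ± 0.00546 of miRNA reads, led by Mir142 at 133 ± 62.6 CPM. Neuron-associated miRNAs took 0.0295% ± 0.00364, led by Mir132 at 112 ± 20.0 CPM and Mir153 at 86.0 ± 2.31 CPM, although the Mir124a, Mir9 and Mir138 genes of this list have identical copies and their counts leave out reads that mapped to several places. Among the other groups, epithelial miRNAs took 0.0125% ± 2.66e-05, led by Mir192 at 102 ± 12.6 CPM (SD, n = 2). The Mir194 genes of the epithelial list have identical copies too. The 2 endothelial miRNAs, Mir126a and Mir126b, took 0.0219% of miRNA reads in replicate 1 and 0.00445% in replicate 2. Hepatocyte and pancreas miRNAs had 9 and 16 reads in replicates 1 and 2, and embryonic stem cell miRNAs had 6 and 4. The imprinted Dlk1-Dio3 locus, a large miRNA cluster, had almost no reads: 40 of its 47 listed genes had no read in either library, and the list had 9 reads in replicate 1 and 6 in replicate 2. That is 0.000119% of miRNA reads (95% exact Clopper-Pearson interval 5.43e-05% to 0.000225%) and 6.08e-05% (2.23e-05% to 0.000132%). Annotated miRNA genes that by repute overlap fragments of other small RNAs took 0.0647% ± 0.00861 (SD, n = 2), led by Mir5099 at 228 ± 48.4 CPM.

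As a list, genes whose main mature arm has an identical copy elsewhere had far lower counts than a preset list of single-copy relatives. Some families, such as Mir24, Mir9 and Mir124a, have no member among the relatives, so this was not a comparison within families. The 57 identical-copy genes had a median of 19.4 CPM in replicate 1 and 15.2 CPM in replicate 2, against 1687 and 1229 CPM for 26 single-copy relatives. The difference was 87.0-fold in replicate 1 and 80.8-fold in replicate 2. The identical-copy genes together took 0.821% ± 0.0137 of miRNA reads and the relatives, which include Mir206, took 47.0% ± 3.92 (SD, n = 2). The highest identical-copy genes were Mir24-2 at 3046 ± 1281 CPM, Mir125b-1 at 1038 ± 143 CPM, Mir196a-2 at 566 ± 347 CPM and Mir181a-1 at 472 ± 129 CPM (SD, n = 2). Multimapping reads, counted outside the genes, came to 22.0% of all reads in replicate 1 and 17.9% in replicate 2, so the counts of identical-copy genes leave out any read that mapped to several places.

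**Figure D2:**
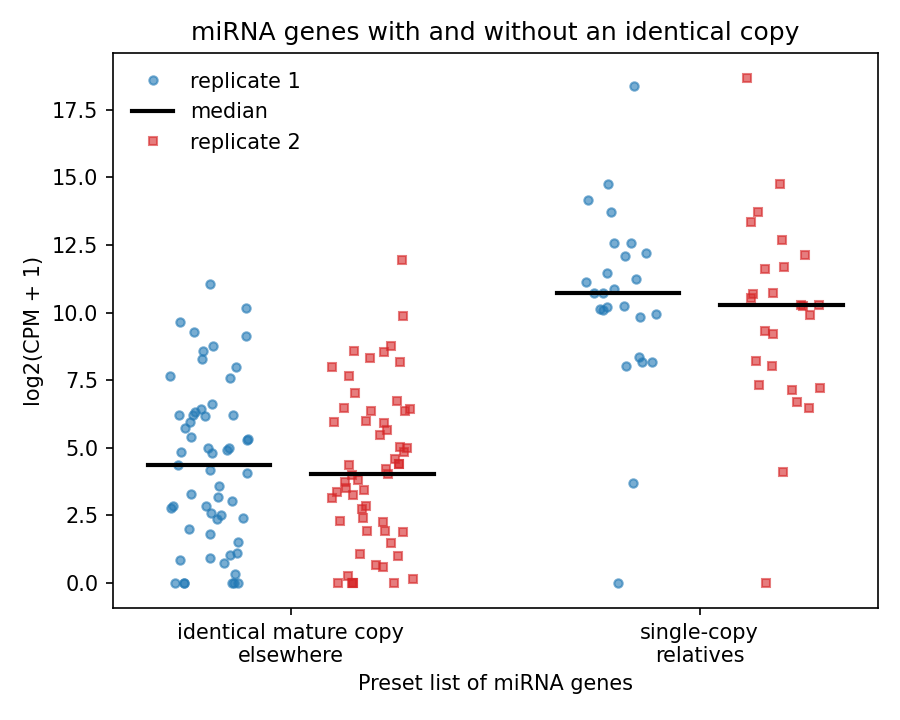
Abundance, as log2(CPM + 1), of miRNA genes with an identical mature copy elsewhere and of single-copy relatives. Each point is a gene (circles replicate 1, squares replicate 2) and black lines are medians; the medians differ 87.0-fold and 80.8-fold in CPM.

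The last comparison was between the 2 libraries. Mir107 was 10.04-fold higher in replicate 1 than in replicate 2, the miRNA gene Gm23935 was 9.77-fold higher and Mir20a was 7.94-fold higher. Mir449a (6.72-fold), Mir374b (6.41-fold), Mir32 (6.18-fold), Mir31 (6.11-fold), Mir98 (6.05-fold), Mir196b (5.63-fold) and Mir34c (5.38-fold) made up the rest of the 10 genes furthest apart. All 10 were higher in replicate 1, and all passed, as the rule that named them required, an exact two-sided binomial test after Benjamini-Hochberg adjustment. Mir107 and Gm23935 share a run of 20 or more bases with another miRNA hairpin, and their values are uncertain. Of the most abundant genes, Mir21a was 2.04-fold higher in replicate 1, Mir378a was 1.62-fold higher in replicate 2 and Mir206 was 1.25-fold higher in replicate 2. The endothelial marker Mir126a was 4.95-fold higher in replicate 1, and the blood-cell marker Mir142 was 2.04-fold higher in replicate 2.

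Of 415 genes tested, 231 differed between the 2 libraries by more than counting error, 105 higher in replicate 2 and 126 higher in replicate 1 (exact binomial test with TMM effective library sizes, adjusted p below 0.05). Among the let-7 family, 9 of 12 members differed, 8 of them higher in replicate 1 and only Mirlet7b higher in replicate 2; adjusted over the list alone, 11 differed, 8 of them higher in replicate 1. Among the myomiRs, 8 of 11 differed, 5 higher in replicate 2 and 3 higher in replicate 1, with the same counts adjusted over the list alone. Among the myogenic modulators, 27 of 32 differed, 18 higher in replicate 1 and 9 higher in replicate 2, again with the same counts adjusted over the list alone. In the Mir17 clusters 9 of 12 tested members differed, 6 higher in replicate 1, and in the fibroblast list 13 of 14 did, 7 higher in replicate 1, with the same counts adjusted over the list alone. Of the identical-copy genes 33 of 49 tested differed, or 36 adjusted over the list alone, and of the single-copy relatives all 25 tested differed by either count. The test finds smaller differences at higher counts. With only genes at 100 or more reads, 205 of 240 tested differed, so lists of unlike abundance cannot be compared by these counts. This test compares these libraries, not conditions.

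Across the 708 genes with a read in either library, which are not independent replicates, Spearman's rho between the libraries was 0.893 and Pearson's r of log2(CPM + 1) was 0.986. The biological coefficient of variation from edgeR was 0.435 over 274 genes. Of those 274 genes, 59 (21.5%) differed 2-fold or more, 45 of them higher in replicate 1 and 14 higher in replicate 2. The chi-square statistic per degree of freedom was 1886, so the counts did not agree within sampling noise, and the libraries were counted as 2 samples, as labelled. The coefficient of variation covers the spread of each gene between the 2 libraries, not errors that both libraries share. Differences between miRNAs smaller than about this replicate error were not resolved, and larger ones may still hold shared errors.

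**Figure D3:**
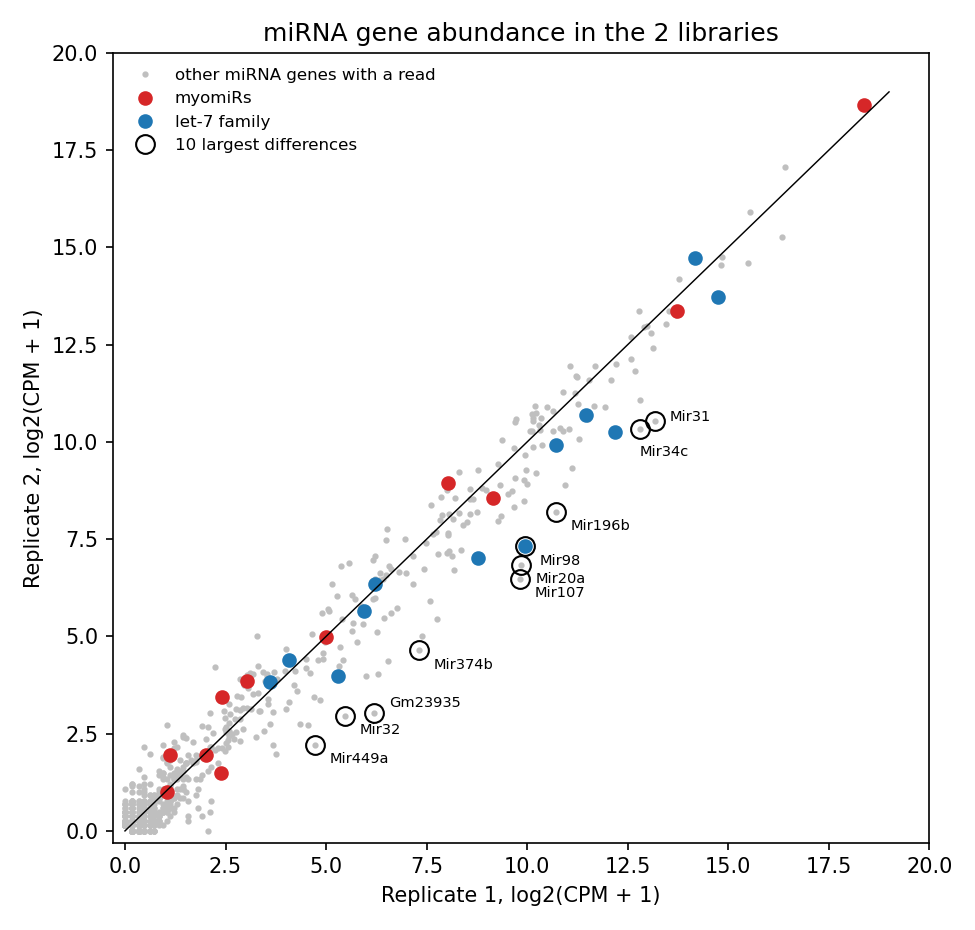
Abundance of each miRNA gene in replicate 1 (horizontal) and replicate 2 (vertical), both as log2(CPM + 1). Red points are myomiRs, blue points the let-7 family, open circles the 10 largest differences, and the line marks equal abundance; all 10 circled genes fall below it, higher in replicate 1.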

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

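The test over genes of related sequence, the test over a range of scaling factors, the value for single-copy relatives without let-7 genes and the resampling interval of the test over neighbouring genes were chosen after results had been seen. The remaining tests were written before their own values were seen, although all but the first on identical copies were written after the counts per gene had been looked at. The series has 1 group of 2 libraries, so outlying libraries and differences between groups could not be looked for.

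Reads outside the main measurement stood above the limit that a count of 0 allows. Multimapping reads numbered 3378438 in replicate 1 and 3295854 in replicate 2. Reads mapped outside miRNA genes numbered 903243 and 1027420. Opposite-strand reads at genes with no miRNA gene on the other strand numbered 75 and 93, with Mir708 (9 and 7 reads) and Mir7654 (4 and 8 reads) the genes above 3 in both libraries.

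Genes with an identical mature copy, such as Mir1a-1, Mir133a-2 and Mirlet7a-1, were listed at least 80.8-fold lower in median CPM than single-copy relatives such as Mir206, Mir133b and Mirlet7i. Outside those lists, among genes with a symbol number below 1000 and a read in each library, the 161 without a run of 20 shared bases had a median at least 7.67-fold above that of the 32 with such a run, which is consistent with reads of shared sequence being set aside as multimapping. In the preset lists, 55 of the 57 identical-copy genes share such a run. Their counts leave out, by construction, reads that mapped to several places. How much of the difference this loss makes stays open. The test as written decided nothing, because multimapping reads, which it required to outnumber the assigned reads, were 0.446 and 0.334 of those. Multimapping reads of any origin were still 54.9 and 40.2 times the reads of all identical-copy genes together. How many of them came from these genes is not known. True differences in abundance between copies and relatives were not tested, and the lists were not matched by family.

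The libraries differed at 231 genes, among them Mir107, Mir20a, Mir31 and Mir34c. Hairpin GC content (standing in for that of the mature miRNA) followed the log2 ratios of 212 genes with a Spearman's rho of 0.277 (permutation p = 0.0002), but removing its linear trend lowered their SD by 3.32%, which argues against GC as the whole cause. Leaving out Mir206 and Mir378a gave 228 genes but moved the TMM scaling by only -0.03 (log2) and so decides nothing, whereas over 41 scaling factors, up to 2 log2 units either way, at least 218 of 413 genes differed, which argues against dominant genes shifting all others alike. Over 83 pairs of neighbouring genes the GC-adjusted ratios correlated at -0.0212 (permutation p = 0.475), which the bound written beforehand would count against a shared shift, but the interval from resampling 32 sets of genes ran from -0.168 to 0.317 and leaves this open. Library preparation and differences between the cultures could both contribute, and no biological explanation was tested.

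Of 12 let-7 family genes 8 were lower in replicate 2 and 4 (Mirlet7b, Mirlet7a-1, Mirlet7a-2 and Mirlet7c-1) were higher, with a median log2 ratio of -0.75 (-0.78 under library totals, -0.72 under DESeq2 size factors) at the 1.78th percentile of lists matched on CPM. The single-copy relatives had a median of -0.56 at the 1.49th percentile, and of -0.42 at the 12.0th percentile without their let-7 genes. The other lists placed this way were the Mir17 clusters (24.8), modulators (43.4), neuronal (44.4), identical copies (45.3), fibroblast (58.25), doubtful genes (73.1) and myomiRs (83.4). These percentiles were not adjusted for the number of lists. Over 40 pairs of genes outside the family whose hairpins share a shorter run of bases, the log2 ratios correlated at 0.496 (permutation p = 0.0005; resampling interval 0.188 to 0.765 over 22 sets). This is consistent with genes of related sequence moving together between the libraries, as a sequence-dependent step of library preparation or read assignment may produce. Shared regulation of related genes was not tested and remains open.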

How the results depend on the processing

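All alternatives reported in this part were planned. No paired analysis was possible because there is 1 group. No ratio changed sign. The count of detected genes stayed within 1.5 times 274 (193 to 327), as did the 231 genes that differed (205 to 230). Leaving out either library gave myomiR shares from 35.5% to 42.8%; with 2 libraries such a value cannot, by construction, move by more than 1 SD. Correlation and variation were compared at 2 decimals, with no replicate spread behind that bound. The depth limits values near 0.396 CPM.

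When strand was ignored, overlapping genes such as Mir378a, Mir30e, Mir191 and Mir24-2 were listed at 0, and this construction moved several values. The rank correlation became 0.882, the coefficient of variation 0.424, and the log2 ratio of Mir206 to the Mir1a copies 16.94. The share of reads became 44.9% for the myomiRs, 7.06% for the myogenic modulators, 0.000908% for blood-cell, 0.0144% for epithelial, 0 for endothelial and 0.000173% for liver and pancreas miRNAs, 0.557% for identical copies, 53.3% for their relatives and 0.0737% for the doubtful genes.

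The rank correlation was 0.963 over genes at 2 CPM or more. The coefficient of variation was 0.450 without a filter and 0.438 with library totals. The cause was not tested.

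With all reads as the denominator, 14 of 15 list shares moved and all 14 were lower, by construction: 20.2% for the myomiRs, 9.20% for the modulators, 2.61% for let-7, 0.562% for the Mir17 clusters, 4.56e-05% for Dlk1-Dio3, 9.97% for fibroblast, 0.00774% for blood-cell, 0.0151% for neuronal, 0.00643% for epithelial, 7.27e-05% for liver and pancreas and 3.04e-05% for stem cell miRNAs, 0.422% for identical copies, 24.2% for their relatives and 0.0331% for the doubtful genes.

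Without Mir206, 14 of 15 shares moved, 12 higher and 2 lower, by construction: 2.09% for the myomiRs, 29.0% for the modulators, 8.19% for let-7, 1.76% for the Mir17 clusters, 0.000142% for Dlk1-Dio3, 31.2% for fibroblast, 0.0244% for blood-cell, 0.0473% for neuronal, 0.0202% for epithelial, 0.000229% for liver and pancreas and 9.48e-05% for stem cell miRNAs, 1.33% for identical copies, 14.6% for their relatives and 0.104% for the doubtful genes.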

Other observations

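The genes in this part were chosen after their values were seen. Several miRNA clusters were well covered in the myotubes. Mir182, Mir96 and Mir183, a cluster best known from sensory cells, together had 4845 CPM, led by Mir182 at 3624 ± 464 CPM (SD, n = 2). Mir210, a miRNA induced by low oxygen, had 2400.1 ± 68.1 CPM and differed little between the libraries. The X-linked cluster that holds Mir322, Mir503, Mir351, Mir542 and the Mir450 genes, all in the list of myogenic modulators, had 31378 CPM over 7 genes, and its members spanned a 1092-fold range from 18.6 CPM for Mir450-1 to 20298 CPM for Mir322. The lower end is uncertain, because Mir450-1 shares a run of 20 or more bases with another miRNA hairpin and leaves out reads that mapped to several places. In the Mir17 cluster on chromosome 14, Mir17 was the highest of 6 members in both libraries, at 6624 CPM in replicate 1 and 3652 CPM in replicate 2, and the lowest was Mir19b-1 in replicate 1 (8.71 CPM) and Mir19a in replicate 2 (16.1 CPM).

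Members of the Mir17 cluster did not differ by the same factor between the libraries. Mir17 was 1.78-fold, Mir18 1.83-fold and Mir20a 7.94-fold higher in replicate 1, and Mir19a had 12.1 CPM in replicate 1 and 16.1 CPM in replicate 2. Mir19b-1 had 66 reads in replicate 1 and 310 in replicate 2, and Mir92-1 had 382 and 369 CPM, but these genes share a run of 20 or more bases with another miRNA hairpin and their values are uncertain.

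Large differences between the libraries were lopsided. Of the 274 genes at 2 CPM or more in both libraries, 17 were at least 4-fold higher in replicate 1 and 1, Mir1949, was at least 4-fold higher in replicate 2. The median log2 ratio of replicate 2 to replicate 1 over these genes was -0.10 with TMM scaling, -0.07 with DESeq2 size factors and -0.13 with library totals.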
